A study of Mus musculus with 4 samples.

How the data were processed

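Total RNA from mouse embryonic fibroblasts at passage 2 and passage 7 was labelled with Cy3 by linear amplification from 0.5 micrograms of RNA, per the labels' protocols, and hybridised to Agilent arrays of a custom design, 2 arrays per passage. The scanner images were read with Agilent Feature Extraction 10.5.1.1, per the file headers, and the deposited spot files give each spot's median and background intensity, a processed signal intensity that is already background-subtracted, and flags for outliers, saturation and signal well above background. The authors' value table holds 1 value per spot and array on a log2 scale. How the authors normalised it is not given in the sources used here; limma is the only tool in the submitters' processing notes, without a version. Set against the scanner files, each of its columns correlated best with the log2 median intensity of the array of the same label (r from 0.9986 to 1.0 across spots). Its column medians were 6.30 and 6.30 for passage 2 and 6.24 and 6.14 for passage 7. Its scale is therefore close to log2 intensity and its direction is that of the signal, while its centring and background treatment stay unknown.

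The arrays carry 43553 probes besides controls, on 43803 spots. Probes were named through the RefSeq accession that the spot files give, with a reference table of mouse genes of assembly GRCm38.p6. Of 31850 probes with such an accession, 31089 (97.6%) matched a symbol, for 17466 genes, and 28.6% of all probes named no gene. The unnamed ones are 5802 probes to long intergenic noncoding RNA exons, 4720 to other transcript designs, 1358 with other accessions, and 292 probes to each strand of the Ink4a-Arf-Ink4b locus. They entered the scaling but not the test of genes. The array design was made on another genome build than the reference table, so no coordinates are given.

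For the main analysis, log2 of the processed signal minus the array's 75th percentile of it over non-control spots was taken. Spots marked as outliers were left out (14 to 61 per array), spots of 1 probe were averaged, and each gene was represented by the probe with the highest mean over the 4 arrays. Genes were kept if well above background on both arrays of at least 1 passage, which left 13823. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 4 arrays, no covariate) with Benjamini-Hochberg adjustment. A gene was called changed at an adjusted p under 0.05 and a change of at least 2-fold. All tests were two-sided, and every adjusted p of a gene comes from limma. Where a gene was not well above background on either array of a passage, its change is given as at least N-fold. That bound is the mean of the brighter passage against, per array of the dimmer one, the higher of the lowest signal well above background and the gene's own. Signal over background was 4.57 and 5.02 on the passage 2 arrays and 4.35 and 3.0 on the passage 7 arrays, which limits what can be said of dim genes.

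Gene lists were fixed before the data were examined: 12 main lists, 2 breast cancer signatures and 8 lists of markers of other cell types. They were tested with limma's camera (preset correlation 0.01, Benjamini-Hochberg over the 22 lists). Every call of camera was lost with a correlation estimated per list, as given beside each list. The directional test fry, which does not compare a list with other genes, was run beside it. Camera's direction, the median and the mean of a list had 1 sign for each list that passed. For the CDK inhibitor list (median -0.04, mean 0.01) and the endothelial markers (median -0.04, mean 0.09) the mean differed in sign from the median and camera's direction.

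The rule for named genes was also fixed before the data were examined. It takes the 8 largest rises and the 8 largest falls among changed genes with a symbol that were measured in both passages, and up to 2 rises and 2 falls from each main list. It adds 10 genes whatever their values, among them Cdkn2a, Cdkn2b, Cdkn1a, Trp53, Mki67, Foxm1, Lmnb1, Il6 and Glb1. Results of some genes that the rule takes are not reported here. Members of the 8 lists of cell type markers were named only where that list shifted, and then after their values were seen. Trophoblast and keratinocyte markers, lists added later for the other observations, were named whether or not the list shifted.

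The alternatives fixed in advance were other background corrections, normalisations, filters on dim probes, choices of probe, variance models, thresholds and list tests, the replicate number as a block, and leaving out each array in turn. When 1 array of a passage is left, it is assumed to vary like the arrays of the other passage. The normexp correction was planned on the mean spot signal, which the spot files used here do not list, and was run on the median spot intensity with an offset of 50. It was run again, as an alternative added later, with the background of spots marked as non-uniform replaced by the array's median background.

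The steps were tested on simulated data drawn with the means and spreads of the 13823 genes, for the comparison of passage 7 with passage 2. With 200 changed genes, the test called 0% of those changed 1.5-fold, 4% of those changed 2-fold, 58% at 3-fold and 96% at 4-fold, with 9 false calls. With 2500 changed genes it called 45% of those changed 2-fold and 94.1% at 3-fold, with 40 false calls. Of the 625 genes changed 2-fold there, 414 passed on p alone, so the 2-fold minimum lowers that share. A simulated shift of the mitosis list was recovered, along with 2 lists that share its genes. The simulated noise was independent between genes and alike in both passages. The false calls may therefore differ on the real arrays, and the preset correlation of camera was not tested.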

Results

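Gene expression was measured in mouse embryonic fibroblasts (MEFs), primary connective tissue cells that divide for a limited number of passages in culture before they stop. Cells at passage 2, which were growing, were compared with cells at passage 7, at the onset of replicative senescence, the lasting arrest that follows repeated passaging. Each passage was read on 2 arrays with 1 colour, and all 4 arrays lay on 1 slide and were read in 1 scan. The 2 passages lay at different positions of the slide, so position and passage cannot be told apart. The labels give 3 independent cultures whose RNA was pooled before expression was measured. The 2 arrays of a passage may therefore be technical repeats, and the p-values of single genes below then measure only the spread between arrays. Those of camera instead compare the genes of a list with all other genes. With the preset correlation of 0.01 they take the genes as almost independent, and they do not measure the spread between cultures. The 75th percentile of the processed signal was 1024 and 1404 on the passage 2 arrays and 964 and 402 on the passage 7 arrays. Between 65.8% and 72.7% of spots were well above background, with the lowest share on the passage 7 replicate 2 array, and no spot was saturated. After normalisation, the SD between the 2 arrays of a passage was 0.33 on the log2 scale at passage 2 and 0.19 at passage 7, as a robust estimate over 13823 genes. The number of arrays limits the precision of every value given here. The series title places the comparison in work on prognostic gene signatures of breast cancer.

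The comparison of passage 7 with passage 2 asked which genes changed as the fibroblasts went from growth to senescence. Among genes measured in both passages, those with the largest rises came from 3 groups. Ivl (involucrin), Kprp and Lce1i encode proteins of the cornified envelope or the outer epidermis. Gzmd, Gzme, Gzmf and Mcpt8 encode serine proteases of the granzyme and mast cell protease families, and Prl8a9 belongs to the prolactin family. Ivl rose 61.4-fold (log2 change 5.94 ± 0.21, SE; adjusted p = 0.005 in limma; the other 15 genes of this group had adjusted p-values of 0.005 or 0.0051, except Lce1i at 0.0071). Kprp rose 36.1-fold, Prl8a9 32.4-fold, Gzmd 32.4-fold, Gzme 30.4-fold, Gzmf 28.8-fold, Mcpt8 28.2-fold and Lce1i 25.2-fold, with SEs of 0.18 to 0.45 on the log2 scale. Prl8a9 was well above background on 1 of the 2 passage 2 arrays, and the granzymes, the prolactin family and the Lce1 genes have close relatives that the probes may not separate. The largest falls among genes measured in both passages were in Hunk, a kinase, which fell by 5.15 ± 0.27 on the log2 scale (35.4-fold), and in Col15a1, the collagen XV chain of basement membranes, which was 28.6-fold lower. Slc38a4, an amino acid transporter, was 25.4-fold lower, the neutrophil chemokine Cxcl5 22.9-fold and the preadipocyte factor Dlk1 22.8-fold. Acan, the cartilage proteoglycan aggrecan, was 20.2-fold lower, Rnf144a 17.9-fold and Gpm6a 15.1-fold. Col15a1 and Acan were well above background on only 1 of the 2 passage 7 arrays. The 1 other probe of each gene gave log2 changes of 5.34 for Ivl, 6.05 for Kprp and -3.30 for Col15a1.

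In all, 2692 of 13823 genes changed by at least 2-fold at an adjusted p under 0.05, of which 1385 rose and 1307 fell. Of 1501 changed genes with further probes, 1480 had the same direction at every other probe. There were 46 genes well above background on both passage 7 arrays and on neither passage 2 array, and 355 with the opposite pattern. Of the changed genes, 42 rises and 140 falls are known only as lower bounds. The passage 7 arrays were dimmer, with 70.6% and 65.8% of spots well above background against 71.9% and 72.7% at passage 2. Lost detection may therefore account for part of both imbalances, and they do not show that more genes were switched off than on. The median change of all genes was 0.20 on the log2 scale, against 0.02 with quantile normalisation, 0.03 with median scaling and -0.06 in the authors' value table. The shifts of gene lists below are therefore given relative to the median of all genes, while changes of single genes include it. Of the changed genes, 51.4% rose, against 41.2% of 3001 genes with median scaling and 36.1% of 2081 genes in the authors' value table. Without the passage 7 replicate 1 array 1252 genes passed, and without the passage 7 replicate 2 array 1143 passed. The planned normexp background correction called 0 genes, against 1273 with quantile normalisation added and 1242 with marked backgrounds replaced.

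**Figure D1:**
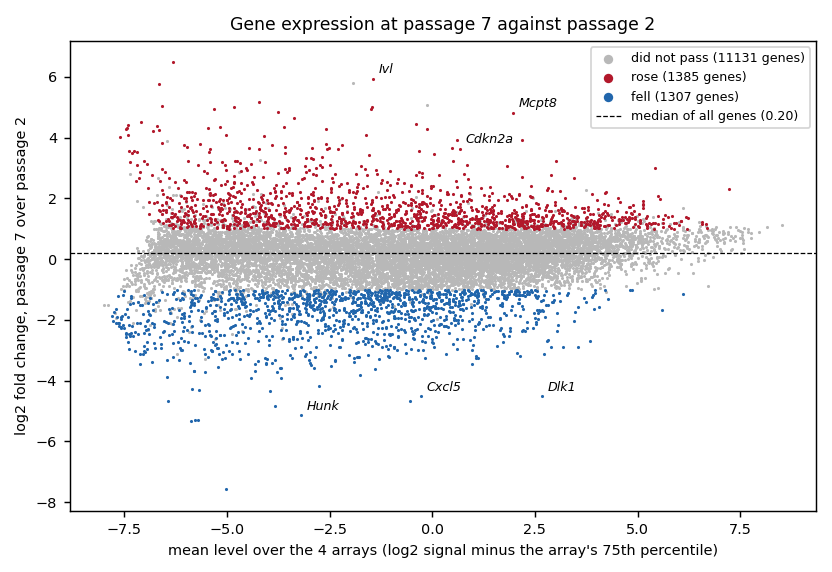
Each point is 1 of 13823 genes, with its mean level over the 4 arrays (log2 processed signal minus the array's 75th percentile) on the horizontal axis and its log2 fold change at passage 7 over passage 2 on the vertical axis. The 1385 genes that rose (red) and the 1307 that fell (blue) spread over the whole range of levels, and the dashed line is the median of all genes, 0.20.

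Genes of cell division fell together. Of 58 tested genes of mitosis and chromosome segregation, 53 fell and none rose (53 and 1 adjusted over the list alone). The list's median was -2.55 on the log2 scale relative to all genes (camera, adjusted p = 8.7e-28; adjusted p = 0.09 with an estimated correlation). Hmmr, a protein of the mitotic spindle, fell by 3.68 ± 0.56 (12.8-fold, adjusted p = 0.016). Its change ranged from -4.47 to -2.88 with 1 array left out, and it was well above background on 1 of the 2 passage 7 arrays. Cit, the citron kinase of cytokinesis, was at least 6.05-fold lower (adjusted p = 0.026), because neither passage 7 array was well above background. Its fitted change ranged from -4.66 to -2.72 with 1 array left out, and with the planned normexp correction it was 0.92 (adjusted p = 0.73). Its call was also lost without a filter on dim probes (adjusted p = 0.058) and with marked backgrounds replaced (adjusted p = 0.68). Of 62 genes of DNA replication and S phase, 44 fell and none rose (45 and 0 adjusted over the list alone), with a median of -1.82 relative to all genes (adjusted p = 7.1e-26; adjusted p = 0.09 with an estimated correlation). Pole2, a subunit of DNA polymerase epsilon, fell by 3.00 ± 0.21 and Clspn, the checkpoint adaptor claspin, by 2.89 ± 0.17 (adjusted p = 0.0051 and 0.005). The transcription and chromatin factors linked to proliferation followed, with 27 of 42 lower and none higher (28 and 1 adjusted over the list alone). Their median was -1.87 relative to all genes (adjusted p = 3.0e-14; adjusted p = 0.19 with an estimated correlation). E2f7 and Mybl2, transcription factors of the cell cycle, fell by 2.96 ± 0.22 and 2.76 ± 0.20. Foxm1, the activator of mitotic genes, fell by 1.96 ± 0.18, and Lmnb1, the nuclear lamina protein lamin B1, fell by 2.35 ± 0.17 (adjusted p = 0.0065 and 0.0052). The other probe of Lmnb1 changed by -3.04 and the 2 others of E2f7 by -2.54 and -2.30. Mki67 was not matched to a probe and was not analysed here. Each of these 3 lists kept its direction and an adjusted p under 0.05 in camera when any 1 array was left out.

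Among the regulators of senescence, Cdkn2a rose most. This locus encodes p16Ink4a and p19Arf, which restrain CDK4/6 and stabilise p53. Its level rose 12.4-fold (log2 change 3.63 ± 0.29, adjusted p = 0.0057), from -1.13 ± 0.45 (SD, n = 2) to 2.50 ± 0.24 relative to the array's 75th percentile, and its 2 other probes changed by 3.67 and 3.74. Its probes are listed under the p16Ink4a transcript, which shares exons with p19Arf, so the transcripts were not told apart. Its neighbour Cdkn2b, which encodes p15Ink4b, was 1.87-fold higher (0.90 ± 0.18, adjusted p = 0.03), short of the 2-fold minimum. The p53 target Cdkn1a, which encodes p21, had a change of 0.30 ± 0.19 (adjusted p = 0.29) and Trp53 one of 0.08 ± 0.20 (adjusted p = 0.77), and neither passed. The 2 other probes of Trp53 changed by -0.16 and 0.49. Relative to the median of all genes, these changes were 0.70 for Cdkn2b, 0.10 for Cdkn1a and -0.12 for Trp53. In the list of CDK inhibitors, pocket proteins and senescence regulators, 3 of 33 genes rose and 4 fell (3 and 5 adjusted over the list alone), and the list did not shift (median -0.04 relative to all genes, adjusted p = 0.87). Kdm6b, a demethylase of histone H3 lysine 27, rose by 1.41 ± 0.23, while Ets2, an activator of the Cdkn2a promoter, fell by 1.72 ± 0.18 and Cdkn1b, which encodes p27, by 1.34 ± 0.19 (adjusted p = 0.018, 0.0081 and 0.015). Kdm6b and Cdkn1b lost their calls without either passage 7 array (adjusted p = 0.057 and 0.092 for Kdm6b, 0.051 and 0.095 for Cdkn1b). Without either passage 7 array, 1 member rose and 1 fell, and without the passage 2 replicate 2 array, 4 rose and 2 fell.

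Of 38 tested p53 target genes, 10 rose and 1 fell (11 and 2 adjusted over the list alone), and the list's median lay 0.33 above all genes (camera, adjusted p = 0.031; adjusted p = 0.29 with an estimated correlation). Perp, a desmosome protein that promotes apoptosis, rose 6.87-fold (2.78 ± 0.19, adjusted p = 0.0051) and the death receptor Fas 4.31-fold (2.11 ± 0.17, adjusted p = 0.0058). The member that fell was Ckap2, a protein of the mitotic spindle that is also counted in the mitosis list, with a change of -1.97 ± 0.32 (adjusted p = 0.018, and 0.051 without the passage 7 replicate 2 array). The shift of this list no longer passed without the passage 2 replicate 1 array (adjusted p = 0.083) or without the passage 7 replicate 1 array (adjusted p = 0.086), nor with no filter on dim probes (adjusted p = 0.052) or the planned normexp correction (adjusted p = 0.34). The count of rises was 6 without the passage 7 replicate 1 array and 4 without the passage 7 replicate 2 array.

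**Figure D2:**
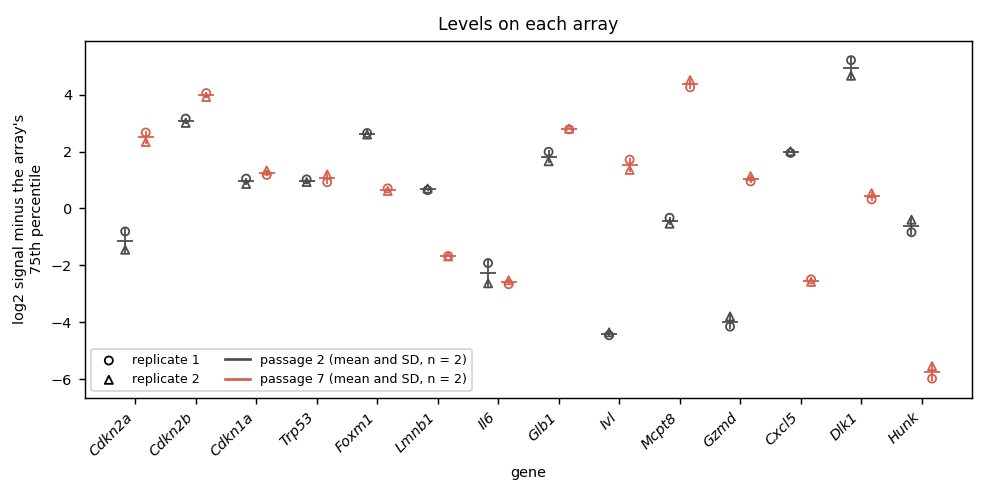
Levels of 14 named genes on each array, as log2 processed signal minus the array's 75th percentile, with circles for replicate 1, triangles for replicate 2 and lines for the mean and SD of the 2 arrays of a passage. Cdkn2a went from -1.13 to 2.50 and Ivl from -4.41 to 1.53 between the passages, while Cxcl5 went from 1.98 to -2.54.

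Secreted factors tied to senescence went both ways. Of 55 tested, 17 rose and 10 fell (20 and 10 adjusted over the list alone), and the list as a whole did not shift (median 0.22 above all genes, camera adjusted p = 0.35). The chemokine Ccl8 rose 13.4-fold (3.75 ± 0.38, adjusted p = 0.0076) and the matrix phosphoprotein Spp1, osteopontin, 4.94-fold (2.30 ± 0.28, adjusted p = 0.011). Cxcl5 fell by 4.52 ± 0.18 and Hgf, the hepatocyte growth factor, by 2.16 ± 0.22 (adjusted p = 0.005 and 0.0076), although the change of Hgf was 0.79 with the planned normexp correction (adjusted p = 0.75) and -3.61 at its other probe. Il6 had a change of -0.32 ± 0.29 (adjusted p = 0.46) and did not pass. With the passage 7 replicate 1 array left out, 6 members rose and 3 fell, and with the passage 7 replicate 2 array left out, 5 rose and 4 fell.

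Of 51 interferon-stimulated genes, 4 rose and 9 fell (5 and 9 adjusted over the list alone), with no shift of the list (median -0.23 relative to all genes, adjusted p = 0.22). Ifit3, an antiviral protein, rose by 2.23 ± 0.18 and the GTPase Irgm1 by 1.64 ± 0.19 (adjusted p = 0.0057 and 0.0095). The chemokine Cxcl10 fell by 2.77 ± 0.18 and the membrane protein Ifitm1 by 2.69 ± 0.38 (adjusted p = 0.005 and 0.014), and Cxcl10 was well above background on 1 of the 2 passage 7 arrays. With the planned normexp correction the change of Cxcl10 was 0.68 (adjusted p = 0.79). The counts were 7 and 10 without the passage 2 replicate 1 array and 2 and 4 without the passage 7 replicate 1 array.

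Genes of the extracellular matrix fell more often than they rose. Of 61 tested, 18 fell and 6 rose, the same counts as adjusted over the list alone, and the median was -0.37 relative to all genes (camera, adjusted p = 0.0033; adjusted p = 0.24 with an estimated correlation). With quantile normalisation 21 fell and 3 rose with a median of -0.68, and with the planned normexp correction the median was -0.86. Besides Col15a1, Eln, the elastin of elastic fibres, fell by 3.62 ± 0.19 (12.3-fold, adjusted p = 0.005). The matrix proteins Spon1 and Tnxb rose by 2.96 ± 0.53 and 1.84 ± 0.28 (adjusted p = 0.023 and 0.017). Spon1 lost its call without a filter on dim probes (adjusted p = 0.054) and Tnxb without the passage 7 replicate 2 array (adjusted p = 0.053). With the passage 7 replicate 1 array left out, 13 fell and 3 rose, and with the passage 7 replicate 2 array left out, 10 fell and 1 rose. Of 33 contractile and TGF-beta-responsive genes, 7 rose and 2 fell, also adjusted over the list alone, and the list did not shift (median 0.01 above all genes, adjusted p = 0.36). With quantile normalisation 3 rose and 4 fell, with median scaling 3 rose and 2 fell, and in the authors' value table none rose and 2 fell. The collagen receptor subunit Itga11 rose by 1.38 ± 0.18 and Ankrd1, a cofactor in the nucleus and sarcomere, by 1.26 ± 0.18 (adjusted p = 0.012 and 0.015). The muscle filament protein Des, desmin, fell by 2.65 ± 0.24 and Csrp2 by 1.37 ± 0.25 (adjusted p = 0.0065 and 0.023). Csrp2 lost its call without either passage 7 array (adjusted p = 0.086 and 0.084), and Ankrd1 was under 2-fold in the authors' value table (0.96), as was Itga11 there (0.93) and with quantile normalisation (0.81). No member of this list rose when either passage 7 array was left out, and 4 rose without the passage 2 replicate 2 array.

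Lysosomal genes that changed were all higher at passage 7. Of 46 tested, 13 rose and none fell (14 and 0 adjusted over the list alone). The median lay 0.55 above all genes (camera, adjusted p = 3.8e-05, and 0.24 with an estimated correlation). The count of rises was 7 with quantile normalisation and 9 in the authors' value table, against 14 with the mean of all probes. None fell in these settings, and the shift passed in each. The protective protein Ctsa, cathepsin A, rose 3.7-fold (1.89 ± 0.32, adjusted p = 0.02) and Ctsh, cathepsin H, 3.09-fold (1.63 ± 0.18, adjusted p = 0.0088). Without either passage 7 array Ctsa had adjusted p-values of 0.05005 and 0.05047 and lost its call, and the other probe of Ctsh changed by 0.65, under 2-fold. Glb1, the lysosomal beta-galactosidase whose activity is a common marker of senescence, was 1.95-fold higher (0.97 ± 0.20, adjusted p = 0.032) and so stayed under the 2-fold minimum, with a change of 0.77 relative to all genes. It passed without the passage 2 replicate 1 array (1.13, adjusted p = 0.032). Without the passage 7 replicate 1 array 3 members rose, and without the passage 7 replicate 2 array 1 rose, although the shift of the list passed in both cases. With the planned normexp correction the median was -0.02 and the shift did not pass (adjusted p = 0.34).

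Of 39 genes of the NRF2 and oxidative stress response, 10 rose and 2 fell, also adjusted over the list alone, and the median lay 0.60 above all genes (camera, adjusted p = 0.008; adjusted p = 0.36 with an estimated correlation). Sod3, the extracellular superoxide dismutase, rose by 1.77 ± 0.18 and Gpx3, a glutathione peroxidase, by 1.66 ± 0.21 (adjusted p = 0.0081 and 0.011). The 2 members that fell were Slc7a11, the cystine transporter, by 2.23 ± 0.18, and Nfe2l2, which encodes NRF2 itself, by 1.19 ± 0.18 (adjusted p = 0.0055 and 0.017). Of 24 genes of sterol biosynthesis and uptake, 4 fell and none rose, also adjusted over the list alone. Their median was -0.82 relative to all genes (camera, adjusted p = 2.3e-04, and 0.29 with an estimated correlation). The count of sterol genes that fell was 7 with quantile normalisation and 6 with median scaling and in the authors' value table. It was 2 with the mean of all probes. With the passage 7 replicate 1 array left out, 2 NRF2 genes rose and no sterol gene fell. With the passage 7 replicate 2 array left out, 3 NRF2 genes rose and 1 sterol gene fell. Nfe2l2 lost its call without either passage 7 array (adjusted p = 0.072 and 0.12). With quantile normalisation and in the authors' value table, 6 NRF2 genes rose and 3 fell. With normexp and quantile normalisation 3 rose and 3 fell, and with the mean of all probes 11 rose and 2 fell. The NRF2 median was 0.38 with quantile normalisation, and with the planned normexp correction it was 0.10 and the shift did not pass (camera, adjusted p = 0.34).

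**Figure D3:**
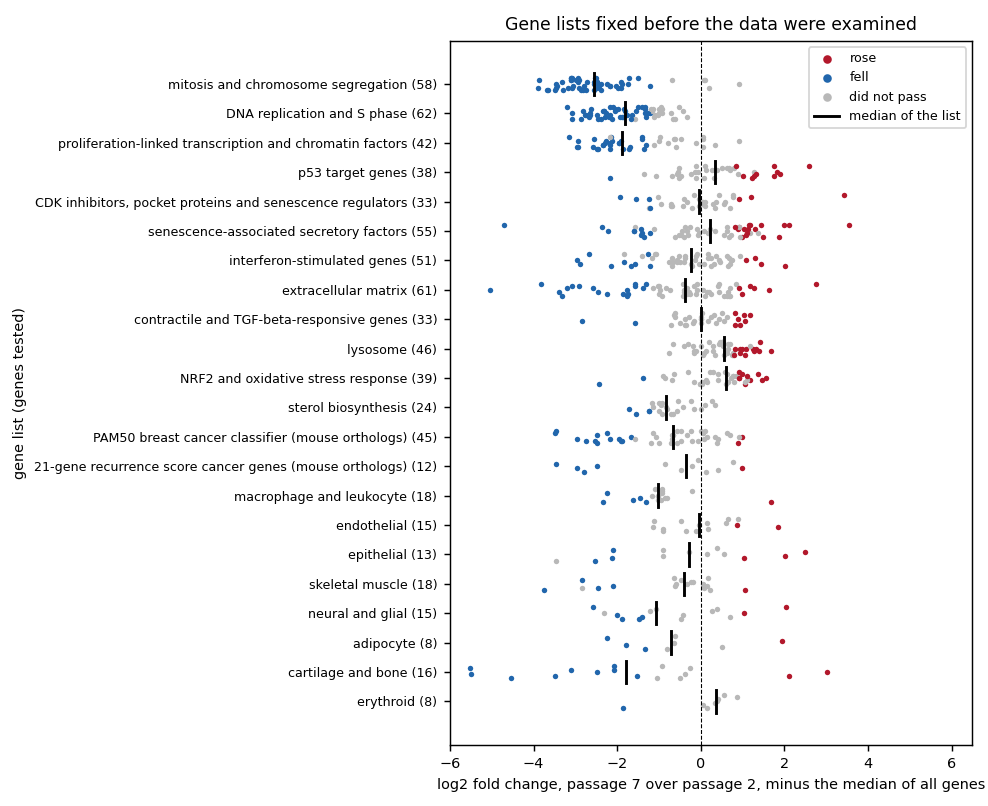
Each point is a tested gene of 1 of the 22 lists, placed by its log2 fold change at passage 7 over passage 2 minus the median of all genes (horizontal axis); black bars are list medians, and red and blue points are genes that rose or fell. The medians of the mitosis, replication and proliferation-linked factor lists lie at -2.55, -1.82 and -1.87, and that of the lysosome list at 0.55.

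Mouse orthologs of 2 breast cancer signatures were followed because of the study's subject. Of 45 tested genes of the PAM50 subtype classifier, 13 fell and 2 rose (14 and 3 adjusted over the list alone), with a median of -0.66 relative to all genes (camera, adjusted p = 3.9e-04; adjusted p = 0.36 with an estimated correlation). Without the genes that a main list also holds, the median was -0.23 relative to all genes and the shift did not pass (adjusted p = 0.39). Of 12 tested cancer genes of the recurrence score, 4 fell and 1 rose, also adjusted over the list alone, and the list's shift did not pass (median -0.35 relative to all genes, adjusted p = 0.091). It passed with median scaling (adjusted p = 0.037), in the authors' value table (adjusted p = 0.047) and without the passage 7 replicate 1 array (median -0.49, adjusted p = 0.045), and the median was -0.17 without the passage 7 replicate 2 array.

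Markers of other cell types that embryo cultures can hold were followed in 8 lists. The cartilage and bone markers stood lower at passage 7, with 9 of 16 lower and 2 higher, also adjusted over the list alone, and a median of -1.80 relative to all genes (camera, adjusted p = 1.1e-04; adjusted p = 0.24 with an estimated correlation). Among them the collagen II chain Col2a1 fell by 2.91 ± 0.18 and the cartilage regulator Sox9 by 1.87 ± 0.20, while Col10a1, the collagen of hypertrophic cartilage, rose by 3.21 ± 0.19 (adjusted p = 0.005, 0.0086 and 0.005). Col9a1 and Ibsp were at least 10.2-fold and 10.9-fold lower, because neither passage 7 array was well above background. The list's median was -0.98 in the authors' value table and -0.96 with the filter on all 4 arrays, where 4 of 11 fell. It was -0.71 with marked backgrounds replaced and -0.61 with normexp and quantile normalisation, and with the planned normexp correction it was 0.14 and did not pass (adjusted p = 0.85). These markers moved in the same direction as the extracellular matrix list. Of 18 macrophage and leukocyte markers, 5 fell and 1 rose, also adjusted over the list alone, with a median of -1.02 relative to all genes (adjusted p = 3.9e-05; adjusted p = 0.36 with an estimated correlation). The macrophage receptor Adgre1 fell by 2.15 ± 0.27 and Csf1r by 1.26 ± 0.25 (limma, adjusted p = 0.012 and 0.028). The count of macrophage markers that fell was 2 without the passage 2 replicate 1 array or without the passage 7 replicate 1 array, and 3 without the passage 7 replicate 2 array, and the list did not pass with the planned normexp correction (median -0.26, adjusted p = 0.58). The other 6 lists did not pass in the main analysis. In them 2 of 15 endothelial markers rose and none fell, 3 of 13 epithelial markers rose and 3 fell, and 1 of 18 skeletal muscle markers rose and 4 fell. Of 15 neural and glial markers 2 rose and 5 fell, of 8 adipocyte markers 1 rose and 3 fell, and of 8 erythroid markers none rose and 1 fell. The adjusted p-values of these 6 lists were 0.9, 0.48, 0.063, 0.063, 0.051 and 0.71, in that order, and their medians lay at -0.04, -0.28, -0.40, -1.08, -0.72 and 0.37 relative to all genes. Skeletal muscle passed with quantile normalisation (adjusted p = 0.031), median scaling (0.018) and the authors' value table (0.0185), and without the passage 2 replicate 2 (0.013) or the passage 7 replicate 2 array (0.0038). The neural list passed with median scaling (0.048) and without the passage 7 replicate 1 array (0.022), and the adipocyte list in the authors' value table (0.048).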

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

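The tests of tiling probes below were chosen after the result was seen. The arrays carry probes that name no gene, which the comparison of genes did not use, and some of them were higher at passage 7 than at passage 2. In a limma fit over all such probes, 134 of 292 probes on the sense strand of the Ink4a-Arf-Ink4b locus were tested, and 2 rose by at least 2-fold at an adjusted p under 0.05. On the antisense strand 153 of 292 were tested and 6 rose, and on neither strand did any probe fall. Among 2298 tested probes to long intergenic noncoding RNA exons 4 rose and 2 fell, and among 2485 tested probes to other transcript designs 10 rose and 9 fell. With quantile normalisation these counts of rises were 4 and 13 for the locus, 34 for the noncoding exons and 64 for the other designs. The lowest adjusted p of a locus probe was 0.034.

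The rise at the Ink4a-Arf-Ink4b locus was weighed because the locus holds Cdkn2a and Cdkn2b: the median change of its tested probes was 0.73 on the sense and 0.72 on the antisense strand, before the shift of other probes is taken off. The median of each strand stood at percentile 100 of 10000 random sets of other non-gene probes of like brightness, whose central range ran from 0.35 to 0.58 for the sense and from 0.37 to 0.58 for the antisense strand. Those sets draw probes independently, while probes with adjacent numbers changed alike (r across probes 0.46 over 73 sense pairs and 0.39 over 91 antisense pairs; permutation p = 3e-05 and 0.00021 with 100000 permutations), but whether numbers follow position is not given. In a bootstrap of 10 runs of 30 adjacent numbers, the median excess over probes of like brightness was 0.29 (0.062 to 0.76) for the sense and 0.26 (0.061 to 0.37) for the antisense strand, and with quantile normalisation 0.21 (-0.011 to 0.72) and 0.22 (0.089 to 0.32), so a shift of all probes of like brightness is argued against as the whole of it on the antisense strand, and on the sense strand only with the main scaling. Which of these probes lie in exons of Cdkn2a, which rose 12.4-fold, is not given. How the strand names relate to the orientation of the genes is not given either, so antisense transcription cannot be read from these rises. Cross-hybridisation, amplified product of both strands and transcription in both directions were not tested and stay open.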

How the results depend on the processing

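The alternatives that replace marked backgrounds and that cross the replicate numbers were chosen after the data were seen, as was the use of the median's sign as a list's direction. No gene was called in opposite directions by the main setting and any alternative run. In every alternative run, the mitosis, replication and proliferation-linked factor lists kept a negative median. Leaving aside runs that omit 1 array or shared list members, the medians of lists that passed ranged from -2.68 to -1.92 for mitosis, -1.95 to -1.39 for replication and -2.00 to -1.29 for proliferation-linked factors. They ranged from -0.86 to -0.35 for extracellular matrix, -1.20 to -0.66 for sterol biosynthesis, -0.71 to -0.35 for PAM50, -1.14 to -0.26 for macrophage and -1.93 to 0.14 for cartilage lists. For lists with a positive median they ranged from 0.081 to 0.41 for p53 targets, -0.021 to 0.57 for lysosome and 0.10 to 0.62 for NRF2. The mitosis, replication and proliferation-linked factor lists kept an adjusted p under 0.05 in all but camera with an estimated correlation. Leaving the single-array omissions aside, lists kept direction and call in 276 comparisons, gained a call in 18, lost it in 18 and turned in 18, and named genes kept both in 606, lost the call in 90 and turned in 6. Of the named genes called in the main analysis, only Cit, Hgf and Cxcl10 turned, with the planned normexp correction. What the arrays limit is dim genes, since the passage 7 replicate 2 array had a signal over background of 3.0 against 5.02 on the brightest array. Where no reason is given below, the cause was not tested.

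Against 2692 changed genes, 51.4% of them higher, quantile normalisation gave 42.3% higher, median scaling 41.2%, the values of the authors 36.1%, a filter on all 4 arrays 55.6% and a trended robust variance 53.4%. Without a filter 1772 of 17438 genes passed. At an adjusted p under 0.01 there were 679 (40.35% higher), and against a 1.5-fold change 1121 (45.05%). The planned normexp correction called 0 genes in limma, with 663 at an unadjusted p under 0.05, and with quantile normalisation added it called 1273 (44.2% higher). With marked backgrounds replaced, normexp called 1242 (60.9% higher). Leaving out 1 array gave between 1143 and 3461 genes, with 40.1% to 59.9% higher. The highest count came without the passage 2 replicate 1 array and the lowest without the passage 7 replicate 2 array. In these fits a gene's own spread comes only from the passage that keeps both arrays. That is passage 2 (SD 0.33) when a passage 7 array is left out, and passage 7 (SD 0.19) when a passage 2 array is. A call lost without a passage 7 array can therefore reflect the larger spread rather than a smaller change.

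The replicate numbers do not pair the arrays: the deviations of arrays with the same number correlated at -0.17 across genes (-0.10 with quantile normalisation). With the replicate block 1193 genes passed (44.6% higher). The crossed pairing called 3063 genes, 54.1% of them higher, with an adjusted p of 0.052 for the p53 list (median 0.33) and 0.046 for skeletal muscle (median -0.40).

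List medians below are relative to all genes. With the planned normexp correction the p53 (0.081), NRF2 (0.10) and macrophage (-0.26) lists lost their calls and the CDK inhibitor list gained one (-0.48). The sign turned for contractile genes (-0.38), lysosome (-0.021), endothelial (0.87), epithelial (1.07), skeletal muscle (0.79), neural (0.42) and cartilage (0.14) lists, and for Cit (0.92), Hgf (0.79), Cxcl10 (0.68), Trp53 (-0.058) and Il6 (0.62). With marked backgrounds replaced it turned for contractile genes (-0.040), endothelial (0.28), epithelial (0.22) and skeletal muscle (0.081) lists, and the recurrence score (-0.33) and adipocyte (-0.95) lists gained calls. Normexp with quantile normalisation turned the interferon (0.0044) and contractile (-0.066) lists, and adipocyte (-0.62) gained a call. With quantile normalisation contractile genes turned (-0.072) and skeletal muscle gained a call (-0.37). Median scaling gave calls to the recurrence score (-0.35), skeletal muscle (-0.40) and neural (-1.08) lists and turned Trp53 (-0.084). The authors' value table gave calls to the recurrence score (-0.25), skeletal muscle (-0.22) and adipocyte (-0.73) lists.

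With no filter the p53 list (0.21) lost its call, contractile genes turned (-0.12) and skeletal muscle gained a call (-0.46). With the filter on all 4 arrays contractile genes (-0.013) and endothelial (0.14) turned and adipocyte gained a call (-0.74). With the mean of all probes the CDK inhibitor list turned (0.0056) and skeletal muscle gained a call (-0.44). Leaving out 1 array gave ranges of 0.17 to 0.50 for p53 targets, -0.00094 to 0.086 for CDK inhibitors, -0.23 to 0.27 for endothelial, -0.49 to -0.17 for the recurrence score, -1.08 to -0.63 for neural and -0.53 to -0.17 for skeletal muscle lists, -0.67 to 0.038 for Il6 and -0.053 to 0.22 for Trp53.

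With an estimated correlation the adjusted p was 0.090 for mitosis and for replication, 0.19 for proliferation-linked factors, 0.29 for p53 targets and sterol biosynthesis, 0.24 for extracellular matrix, lysosome and cartilage, and 0.36 for NRF2, PAM50 and macrophage lists. These values do not separate an effect of correlation from that of the few degrees of freedom. With fry the macrophage list lost its call (0.065), and the recurrence score (0.010), neural (0.022) and adipocyte (0.029) lists gained one. Without genes of another main list, PAM50 lost its call (-0.23). The SD between arrays with quantile normalisation was 0.315 at passage 2 and 0.182 at passage 7, against 0.334 and 0.192.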

Other observations

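The families and genes in this part were chosen after their values were seen, as were the tests of spot noise and of histone genes. The genes around the largest rises belong to clustered families. Of 8 tested prolactin-family genes 7 rose and none fell, with a median 3.08 above all genes on the log2 scale, and 7 rose with quantile normalisation and in the authors' value table as well. Of 9 Lce genes of the cornified envelope 6 rose, of 4 Sprr genes 2, of 7 granzymes 4, of 3 mast cell proteases 2 and of 5 Serpinb9 genes, serine protease inhibitors, 4, and none of these fell. Their medians also lay above all genes with quantile normalisation and in the authors' value table. Of the 5 Serpinb9 genes 1 rose in that table, with a median of 0.73 against 2.17, 1 of the 3 mast cell proteases, with 1.06 against 4.02, and 3 granzymes, 5 Lce genes and 2 Sprr genes. Prl3a1 rose 19.6-fold (4.29 ± 0.19, SE, adjusted p = 0.005 in limma). Of 9 Rhox genes 3 rose (1 in the authors' value table), with a median of 0.30. The homeobox gene Rhox2d was at least 24.3-fold higher and the placental cathepsin Ctsll3 at least 12.6-fold, since neither was well above background at passage 2. Among genes that were well above background at passage 2 alone, Scara5, a ferritin receptor, was at least 40.3-fold lower and Tmem26 at least 11.4-fold.

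In a scan of 176 gene families of 10 or more genes, camera gave 11 with an adjusted p under 0.05, none of them with an estimated correlation (adjusted p = 0.996). Of 16 nucleoporin genes 5 fell and none rose, with a median of -1.09 relative to all genes (adjusted p = 7.1e-04), and of 301 Zfp zinc finger genes 37 fell and 10 rose (median -0.42, adjusted p = 7.1e-04). Both kept the direction and the call with quantile normalisation, in the authors' value table and without either passage 2 array. Of 22 Cox genes, mostly of the mitochondrial cytochrome c oxidase, 7 rose and none fell (median 0.74, adjusted p = 0.032), with a median of 0.55 with quantile normalisation and 0.67 in the authors' value table. Without the passage 2 replicate 2 array the Cox median was 0.32 and the adjusted p 0.12. The ribosomal Rpl genes had a median of 0.42 (adjusted p = 0.012), but of -0.0014 with quantile normalisation (adjusted p = 0.86).

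Involucrin, Lce genes, granzymes and prolactin-family genes are better known from epidermis and placenta than from fibroblasts, so an outgrowth of other cells was weighed. Keratinocytes are argued against only as far as their keratins go: none of 7 keratins rose, and Krt14 fell by 2.33 ± 0.32. The 25 tested markers had a median 0.073 above all genes (camera, adjusted p = 0.69). However, Grhl3, Dsp, Perp and 4 other markers rose, and only Krt14 fell. With 7 of 25 higher, the share of rises was larger than the 1385 of 13823 genes, so the other markers as a set do not argue against such cells. However, Trp63 (-0.99 ± 0.31), Cdh1 (-3.27 ± 1.27) and Lgals7 (-1.03 ± 0.46) were lower without passing. Cdh1 was well above background on only 1 of the 2 passage 7 arrays. For trophoblast, the 16 tested markers, as set before their test, decided nothing. Eomes, Prl2c2 and Prl3d1 rose, 4 fell and the list did not shift (median 0.18 above all genes, camera, adjusted p = 0.94). Prl2c2 and Prl3d1 belong to the prolactin family that prompted the question, so their rises restate it. Of the other markers only Eomes rose (2.93), while Krt8 (-1.90), Krt18 (-1.92) and Slco2a1 (-1.70) fell. Plac1 also fell, but it was not well above background on either passage 7 array, so the size of its fall was not measured. An outgrowth of trophoblast cells stays open. Signal shared between related genes of a family and a change within the fibroblasts themselves stay open, since probe sequences were not used here.

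The 2 passage 2 arrays differed more than the 2 passage 7 arrays (SD 0.33 against 0.19), and 143 against 43 genes lay over 4-fold apart. Noise of single spots is argued against, since the difference between the passage 2 arrays correlated at 0.74 between 2 probes of one gene, across 6819 genes. A growth state that moves all mitosis genes by over 0.5 on the log2 scale is argued against. Their median difference was 0.0025, with 29 up, 29 down and quartiles at -0.25 and 0.25, while a smaller shift stays open. For the 62 genes of DNA replication and S phase it was -0.10, with 26 up and 36 down, within the -0.19 to 0.084 of random lists. A different yield of transcripts without a poly(A) tail is consistent with the 55 replication-dependent histone genes, whose median was -0.96 on replicate 2 relative to replicate 1, outside the -0.31 to -0.0028 of random lists, though it also differed between the passage 7 arrays (0.23, random lists 0.0075 to 0.17), and the source of the rest of the difference was not tested. This bears on histone genes at passage 7: 17 rose and 2 fell, with a median of 0.46 relative to all genes, but 15 rose and 10 fell without the passage 2 replicate 2 array (median -0.10), and 33 rose and 2 fell without replicate 1 (median 1.25).

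In 10 genes the 2 arrays of a passage differed by over 5 on the log2 scale. For Mrpl46 the passage 2 difference was -10.4 and for Smox -10.1, each read from 1 probe.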
